A study of Homo sapiens with 12 samples.

How the data were processed

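RNA-seq was done on HTR-8/SVneo cells, an immortalised human extravillous trophoblast line made from early placenta. Cells were exposed for 24 h to DMSO vehicle (0.1% v/v) or to 1 or 10 µM tris(4-chlorophenyl)methanol (TCPMOH), an organochlorine compound, in the same amount of DMSO. Per the labels' protocols, 400000 cells were seeded per well, RNA was extracted with a column kit, and stranded libraries were made after poly-A selection. The labels give 4 independent experiments, and each of the 3 groups holds 4 libraries. The labels state passages 25 to 35 in the growth protocol and 78 to 84 in the treatment protocol, and this difference was not resolved. The series title also names a related compound, TCPM, which was not analysed here.

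The deposited values are raw counts per gene symbol, with 59251 symbols in each of the 12 libraries. Per the submitters' processing notes, the authors named STAR, featureCounts and DESeq2 and the human builds GRCh38 and hg38, and the file headers also name STAR for the mapped reads. Tool versions, the annotation release, the strand setting of the counting and the treatment of reads with several matches were not given in the sources used here. Counts of overlapping or antisense genes, and of close copies such as TRIM16 and TRIM16L, are therefore uncertain. Of the symbols, 57842 were current RefSeq symbols, and coordinates were taken from RefSeq on GRCh38.p14.

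Differential expression was tested on the deposited counts with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. All 12 libraries entered 1 fit with a mean per group, TMM normalisation and the default filter of edgeR on low counts, which left 15134 genes. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with 0.05 as the threshold, and standard errors are those of the fitted log2 fold change. Levels are given as TMM-normalised CPM, as mean ± SD over the 4 libraries of a group. Library totals ran from 17.6 to 33.2 M counts, and calls of genes at a few CPM rest on few reads per library. Counts were simulated with the real means, library sizes and dispersions, drawn independently for each gene. The 200 changed genes had a mean of at least 5 CPM, so recovery of lower genes was not measured. The fit was tested on these counts at 10 µM against DMSO. It recovered 65.7% of genes changed by 1.25-fold, 97.0% of those changed by 1.5-fold and 100% of those changed by 2-fold, over 14949 genes. For 1 µM against DMSO the shares were 68.7%, 100% and 100% over 14954 genes. For 10 µM against 1 µM they were 73.1%, 98.5% and 100% over 14964 genes. The simulated libraries had no trend on GC content or length and no difference between experiments. Recovery in the real fits may therefore be lower, also where fewer than 200 genes change.

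Gene lists (33, with 741 entries, all matched to symbols in the files) were written before the data were examined, as were the groups, the tests, the other settings and the rule for named genes. The 30 lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01. Tests with an estimated correlation and with fry stand beside it. Named genes were, per comparison, the 10 largest rises and the 10 largest falls among called genes with a mean of at least 5 CPM and no overlap between the groups. Up to 4 members of each list with the smallest adjusted p were added, with a fixed set of genes that could be named in any comparison. Where no gene was called, the 3 genes with the smallest p in each direction were named as not passing. At 10 µM against 1 µM, 1 further gene met the rule and is not reported here.

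Alternatives were DESeq2 1.42.0, limma-voom, other normalisations and filters, fits of only the groups compared, stricter thresholds, a block on the replicate number, split controls and leaving out each library. Offsets fitted to each library's trend on GC content and then on transcript length, alone or with the block, and a fit without the 3 libraries numbered 1, were added after seeing the data. With these offsets the correlation of fold change with length was -0.0251 to 0.0206 over the 3 comparisons, but that with GC content stayed at 0.114 at 10 µM against 1 µM and -0.0965 at 1 µM against DMSO. Repeated offsets, with the 2 trends refitted in turn 10 times, were therefore added as well and left GC correlations of 0.00175 to 0.00604. Length and GC content were those of the longest annotated transcript of each gene, which need not be the one expressed. The offsets used such values for 92.1% of the tested genes. In simulated counts for 10 µM against DMSO with a length trend and no changed gene, 1616 of 15134 genes were called without the offsets and 0 with them. That trend was built on the same lengths that the offsets use, so the simulation does not test trends of another form. Libraries of a group were also compared in pairs, and a chi-square per degree of freedom from 2.56 to 13.2 left no pair that agreed within sampling noise. A setting for identical files, foreseen at the outset, was therefore not run. Figures were drawn with matplotlib 3.10.9.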

Results

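The 12 libraries held 17.6 to 33.2 M counts and 21654 to 24719 detected genes each. The DMSO group held 18.6 to 27.2 M counts, the 1 µM group 18.9 to 33.2 M and the 10 µM group 17.6 to 32.9 M. The first principal component took 17.6% of the variance and set 10 µM replicate 1 at -33.4, apart from the other libraries of its group at 3.03 to 6.43. DMSO replicate 1 (-11.1) and 1 µM replicate 1 (-13.3) were negative as well. All libraries numbered 2 to 4 were positive, from 1.91 to 15.0, so this component set the number 1 apart in every group. The common biological coefficient of variation was 0.0688.

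The comparison of 10 µM TCPMOH with vehicle asked which genes differed after 24 h. Among called genes with a mean of at least 5 CPM and no overlap between the groups, MMP1 and CXCL8 rose most and HMOX1 and CPA4 fell most. MMP1, an interstitial collagenase, rose from 32.6 ± 12.8 to 90.2 ± 28.4 CPM (log2 fold change 1.48, SE 0.21, adjusted p = 0.000507, n = 4 per group, edgeR). CXCL8, the chemokine interleukin-8, rose from 3.99 ± 1.10 to 10.6 ± 2.30 CPM (1.42, SE 0.19). HMOX1, the haem oxygenase induced by oxidative stress, fell from 122.1 ± 10.7 to 59.2 ± 14.3 CPM (-1.05, SE 0.13, adjusted p = 0.000135). CPA4, a carboxypeptidase, fell from 39.1 ± 1.51 to 22.6 ± 1.05 CPM (-0.79, SE 0.07, adjusted p = 2.1e-06).

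Of 15134 genes tested, 207 were called, 142 higher and 65 lower. In 182 of these every 10 µM library lay on one side of every DMSO library, which chance gives for 2.86% of genes not chosen by a test. The called genes were chosen on the same libraries, so this share is no test of them. Most changes were small, with a median size of 0.42 on the log2 scale, and 12 genes changed by at least 1. On GRCh38.p14, MMP1 lies on chromosome 11 at 102789919 to 102798160, HMOX1 on chromosome 22 at 35381096 to 35394207 and CPA4 on chromosome 7 at 130293161 to 130324180. Among called genes with a mean of at least 5 CPM and no overlap, the largest rises besides MMP1 and CXCL8 were in ESM1 (1.20), TMEM158 (1.14), the chromatin factor HMGA2 (1.06), DOCK4 (1.02), the collagen receptor subunit ITGA2 (0.98), the circadian factor NPAS2 (0.90), TMEM200A (0.85) and CDCP1 (0.82). Within the same limits, the largest falls after HMOX1 and CPA4 were in the GDNF receptor GFRA1 (-0.75), the inhibitor of DNA binding ID2 (-0.65), SAMD11 (-0.63), JPH2 (-0.60), ID4 (-0.60), TAGLN (-0.58), the inhibitory SMAD gene SMAD6 (-0.57) and the growth factor TGFB2 (-0.55). The count was 134 without DMSO replicate 2 and 102 without DMSO replicate 4. With the replicate number as a block it was 412, and all 207 genes were among these. ID4 lost the call without DMSO replicates 2, 3 or 4 or 10 µM replicates 2 or 4 (adjusted p 0.0674 to 0.117), and TAGLN without DMSO replicates 1, 2 or 4 or 10 µM replicates 2, 3 or 4 (0.0511 to 0.140).

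**Figure D1:**
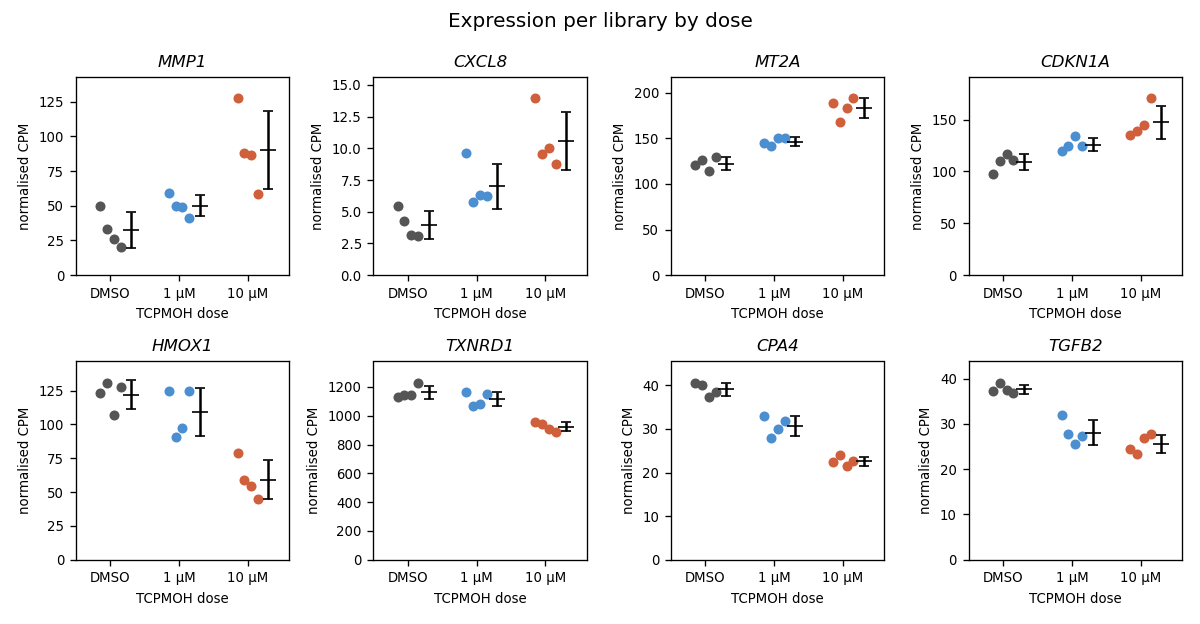
Normalised counts per M of 8 genes in each of the 12 libraries (points) by TCPMOH dose, with the group mean and SD (bars, n = 4). At 10 µM MMP1 averaged 90.2 CPM against 32.6 CPM in DMSO, and HMOX1 averaged 59.2 against 122.1 CPM.

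Targets of NRF2, the oxidative stress transcription factor, were lower at 10 µM as a list. Of 20 tested members 7 fell, 13 did not pass and 0 rose, and 12 were lower when adjusted over the list alone. Beside HMOX1, the thioredoxin reductase TXNRD1 fell from 1162 ± 45.0 to 923.9 ± 30.5 CPM (-0.33, SE 0.04), NQO1 by a log2 change of -0.34 and the ferritin heavy chain FTH1 by -0.31. The list's median was -0.26 and its adjusted camera p was 0.0112 with an estimated correlation.

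Genes of NF-κB signalling and inflammatory cytokines were higher. Of 18 tested members 4 rose and 14 did not pass, and 8 were higher when adjusted over the list alone. These were CXCL8, the inhibitor of apoptosis BIRC3 (0.81, SE 0.10), the NF-κB feedback gene TNFAIP3 (0.65, SE 0.12) and the chemokine CXCL1 (1.10, SE 0.26). CXCL1 was near the threshold, and its call was lost without DMSO replicates 3 or 4 or 10 µM replicates 1, 2 or 3 (adjusted p 0.0546 to 0.152). The list had an adjusted p = 0.0112 with an estimated correlation.

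Genes of extravillous trophoblast invasion were higher as a list, with 6 of 22 tested members up, 1 down and 15 not passing. The list as written holds protease inhibitors such as TIMP1 and SERPINE1 beside proteases, and invasion itself was not measured. Adjusted over the list alone, 11 were higher and 1 lower. The plasminogen activator PLAU rose by 0.58 (SE 0.08) and its receptor PLAUR by 0.62 (SE 0.11). DIO2, a deiodinase, was lower at -1.42 (SE 0.27), at a low level of 0.710 ± 0.181 against 1.94 ± 0.415 CPM. The list had an adjusted p = 0.0112 with an estimated correlation.

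Targets of p53 were higher, with 3 of 21 tested members called, 18 not passing and 9 higher when adjusted over the list alone. These were the stress cytokine GDF15 (0.65, SE 0.09), the cell cycle inhibitor CDKN1A (0.44, SE 0.07) and the p53 ubiquitin ligase MDM2 (0.27, SE 0.06). The call of MDM2 was lost without DMSO replicates 2 or 4 or 10 µM replicates 2, 3 or 4 (adjusted p 0.0504 to 0.107). The list had an adjusted p = 0.0311 with an estimated correlation.

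**Figure D2:**
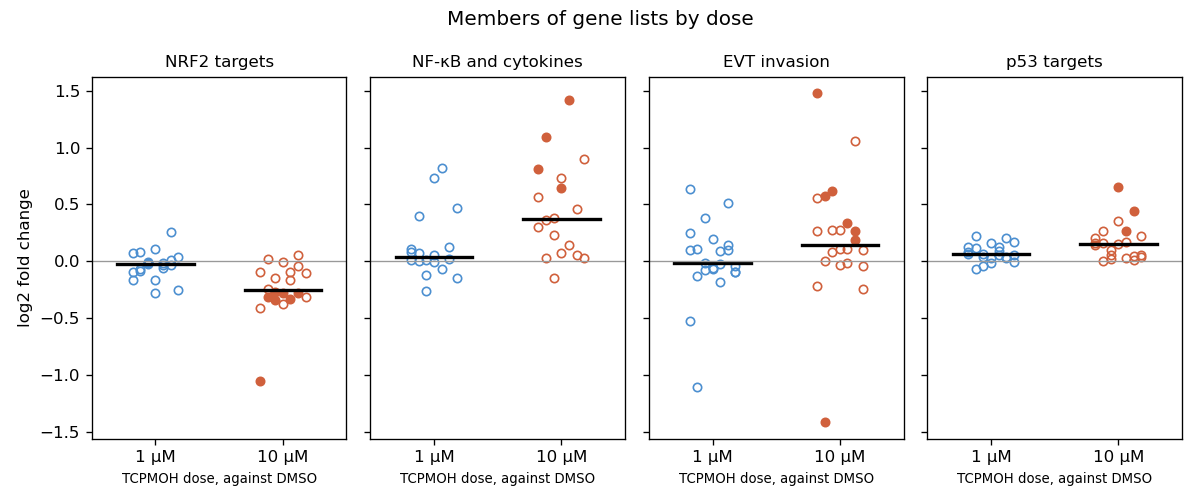
Log2 fold change against DMSO of each tested member (points) of 4 gene lists at 1 and 10 µM TCPMOH. Filled points passed an adjusted p of 0.05 over all genes and black lines are medians. At 10 µM the median was -0.26 for NRF2 targets and 0.37 for NF-κB and cytokine genes. No member passed at 1 µM in this fit, which had no replicate block.

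Camera called 14 of the 30 lists at 10 µM, 6 up and 8 down, and the 4 above kept the call with an estimated correlation. Immediate early genes were up, with 5 of 22 members higher, among them KLF6 (0.31), the ERK phosphatase DUSP6 (0.56) and SPRY2 (0.43), and adjusted p = 0.298 with an estimated correlation. Hypoxia and glycolysis genes were up, with NDRG1 (0.47), P4HA1 (0.23) and HK2 (0.35) higher and ADM (-0.30) lower of 29, and adjusted p = 0.298 with an estimated correlation. Placental hormones and growth factors were up with 0 of 10 members called, and adjusted p = 0.364 with an estimated correlation. Mesenchyme and matrix genes were called down with a mean of -0.05 but a median of 0.01, and adjusted p = 0.255 with an estimated correlation. In that list TGFB2, THBS1 (-0.43) and CCN2 (-0.35) were among 5 lower members of 21, and the filament gene VIM (0.33) was higher. Stromal markers were down with POSTN (-0.51) the member called of 13, and adjusted p = 0.364 with an estimated correlation. Genes of the ATF4 response were down, with PHGDH (-0.22) lower and GDF15 higher of 30, and adjusted p = 0.701 with an estimated correlation. Heat shock proteins, G2/M genes and fatty acid synthesis genes were down with 0 members called, and their adjusted p with an estimated correlation was 0.364, 0.425 and 0.217. Mitochondrially encoded mRNAs were down with 0 of 13 members called, CYTB at -0.57 and ATP6 at -0.57, and adjusted p = 0.364 with an estimated correlation. PHGDH lost its call without any of DMSO replicates 1, 2 and 4 or 10 µM replicates 2, 3 and 4 (adjusted p 0.0936 to 0.179), HK2 without DMSO replicates 2, 3 or 4 or 10 µM replicates 1 or 3 (0.0972 to 0.153), P4HA1 without DMSO replicates 2 or 4 or 10 µM replicates 2 or 4 (0.0709 to 0.115) and SPRY2 without DMSO replicate 4 (0.0590). Camera called 9 lists without DMSO replicate 2, 9 without 10 µM replicate 1 and 8 without 10 µM replicate 2. ATP6 passed without 10 µM replicate 3 (adjusted p = 0.0380).

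The mitochondrial mRNA share was 0.930 ± 0.0622% of counts in DMSO, 0.739 ± 0.187% at 1 µM and 0.755 ± 0.155% at 10 µM (n = 4 each). The exact permutation p was 0.0571 at 10 µM and 0.114 at 1 µM against DMSO, and 0.286 and 0.357 after adjustment over 15 comparisons of library measures.

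The other 16 lists were not called at 10 µM, with adjusted camera p from 0.112 to 0.719. They covered cholesterol synthesis, LXR, PPAR, ER chaperones, AHR, steroidogenesis, sex steroid receptors, trophoblast identity, endothelial markers, interferon response, nuclear oxidative phosphorylation, G1/S, apoptosis, autophagy, replication histones and ribosomal proteins. Among their members the integrin ITGA6 (0.60, SE 0.08), EGFR (0.43, SE 0.10) and the cholesterol exporter ABCA1 (0.48, SE 0.09) rose. The call of EGFR was lost without DMSO replicates 2, 3 or 4 or 10 µM replicates 1 or 3 (adjusted p 0.0550 to 0.124). CYP1A1, the marker enzyme of AHR activation, stood at 4.23 ± 1.01 against 3.13 ± 0.504 CPM (log2 fold change 0.41, adjusted p = 0.414). CYP1B1 was at -0.14 (adjusted p = 0.899), HMGCR at -0.04 (0.868), LDLR at -0.08 (0.763), DDIT3 at 0.03 (0.954) and ATF3 at -0.15 (0.537). The lists of metallothioneins, immune markers and PXR or CAR targets had 4, 2 and 3 tested members and were not tested as lists. Among metallothioneins, MT2A on chromosome 16 at 56608584 to 56609497 rose from 122.2 ± 6.73 to 183.1 ± 11.3 CPM (0.58, SE 0.05, adjusted p = 2.5e-06) and MT1X rose by 0.43 (SE 0.09), though the latter had an adjusted p of 0.0504 without DMSO replicate 2. Among immune markers, the lysosomal protein CD68 rose by 0.53 (SE 0.09).

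The comparison of 1 µM TCPMOH with vehicle asked whether the lower dose changed expression. At 1 µM against DMSO, 0 genes passed in edgeR, with a smallest adjusted p of 0.136, while 1446 genes had an unadjusted p under 0.05 against 756.7 by chance. That count was 1107 with the repeated offsets and 1918 with the replicate number as a block. It ran from 1009 to 1663 without 1 library of the compared groups. Without offsets the fold changes correlated with transcript length (-0.217) and GC content (-0.229), so genes were not independent and the excess was not tested. The lowest p-values among rises were in MT2A (0.26, SE 0.05), the arrestin ARRDC3 (0.38, SE 0.08) and GSTO1 (0.24, SE 0.05), each with an adjusted p of 0.143. Among falls they were in TGFB2 (-0.42, SE 0.07), CPA4 (-0.35, SE 0.07) and the collagen COL5A1 (-0.28, SE 0.05), each with an adjusted p of 0.136. HMOX1 was at -0.16 (adjusted p = 0.696), NQO1 at -0.02 (0.929), CDKN1A at 0.21 (0.313), CXCL8 at 0.82 (0.170) and MMP1 at 0.64 (0.340). The last 2 lay above 0.585, the log2 size of a 1.5-fold change, which the fit recovered in 100% of simulated genes. The 0 calls therefore do not exclude changes of that size. DESeq2 called 40 genes, 6 higher and 34 lower, and limma-voom called 0. With no filter on low counts edgeR called 194 genes, all 194 of which pass the filter, and without 1 µM replicate 1 it called 1 gene. Without 10 µM replicate 1, which enters the shared fit, it called 2 genes, and with repeated offsets for GC content and length also 2. With the replicate number as a block edgeR called 51 genes, 12 higher and 39 lower. MMP1 (0.67, adjusted p = 0.000976) and CXCL8 (0.81, 0.00959) were among them. The labels do not say whether libraries with the same number were made together.

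Camera called 7 lists at 1 µM, 4 up and 3 down, and 0 kept the call with an estimated correlation. Ribosomal proteins (median 0.08, adjusted p = 0.643 with an estimated correlation) and nuclear oxidative phosphorylation genes (0.08, adjusted p = 0.643 with an estimated correlation) were up with 0 members called. Hypoxia and glycolysis genes (0.06) and p53 targets (0.06) were up with adjusted p = 0.643 and 0.617 with an estimated correlation. Mitochondrially encoded mRNAs (-0.31), stromal markers (-0.21) and mesenchyme and matrix genes (-0.04) were down, each with adjusted p = 0.617 with an estimated correlation.

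The comparison of 10 µM with 1 µM asked how the doses differed. HMOX1 was lower at 10 µM than at 1 µM, at 59.2 ± 14.3 against 109.4 ± 17.8 CPM (-0.89, SE 0.13, adjusted p = 0.00286, edgeR). BIRC3 (0.73, SE 0.10) and GDF15 (0.66, SE 0.09) were higher with the same adjusted p. MT2A was higher by 0.32 (SE 0.05), CDCP1 by 0.64 (SE 0.11) and AHNAK2 by 0.68 (SE 0.10), while CPA4 was lower at -0.44 (SE 0.07).

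In all, 178 genes were called, 157 higher and 21 lower at 10 µM, 0 of them by a log2 change of at least 1. The groups were fully separated in 173, where chance gives 2.86% for genes not chosen by a test on the same libraries. Further rises were in TMEM158 (0.91), HMGA2 (0.83), IGFBP5 (0.73), the nuclear envelope protein SYNE2 (0.69) and the cadherin FAT1 (0.67). Further falls were in TAGLN (-0.58), ID2 (-0.51), TRIM16L (-0.43), HTRA3 (-0.38), ID3 (-0.38), ABHD4 (-0.37), TRIM16 (-0.35) and IDH1 (-0.33). Without 1 µM replicate 4 the calls of TMEM158, IGFBP5, SYNE2, FAT1, TAGLN, ID2, HTRA3, ID3, ABHD4, TRIM16 and IDH1 were lost (adjusted p 0.0589 to 0.180). Without 1 µM replicate 3 HMGA2 (0.0583) and 8 of those genes lost theirs, and some of them also without 1 µM replicates 1 or 2 or 10 µM replicates 2, 3 or 4, while TRIM16L kept its call in every such fit. The count fell to 100, 49 and 20 without 1 µM replicates 1, 3 and 4, and to 83 and 31 without 10 µM replicates 2 and 3. With the replicate number as a block it was 511, and all 178 genes were among these.

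The rises fell on genes with long transcripts, by the longest annotated transcript of each gene. The median transcript length of the genes higher at 10 µM was 8178 bases against 3535 bases for all genes with a length. The Spearman correlation across genes of a library's deviation with transcript length averaged 0.106 ± 0.106 at 10 µM and -0.160 ± 0.122 at 1 µM. These groups did not overlap (n = 4 each, exact permutation p = 0.0286, the smallest this design allows, and 0.214 after adjustment over 15 comparisons). The DMSO libraries averaged 0.0115 ± 0.244 and ran from -0.208 to 0.273 (n = 4), so trends of either sign also arose without TCPMOH. With offsets for GC content and length, 120 genes were called, 88 higher and 32 lower, and 96 of them were among the 178. These offsets left the correlation of fold change with GC content at 0.114. With repeated offsets, which left it at 0.00604, 87 genes were called, 63 higher and 24 lower, 73 of them among the 178. The genes called higher still had a median length of 6001 bases with the first offsets and 6215 with the repeated ones.

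**Figure D3:**
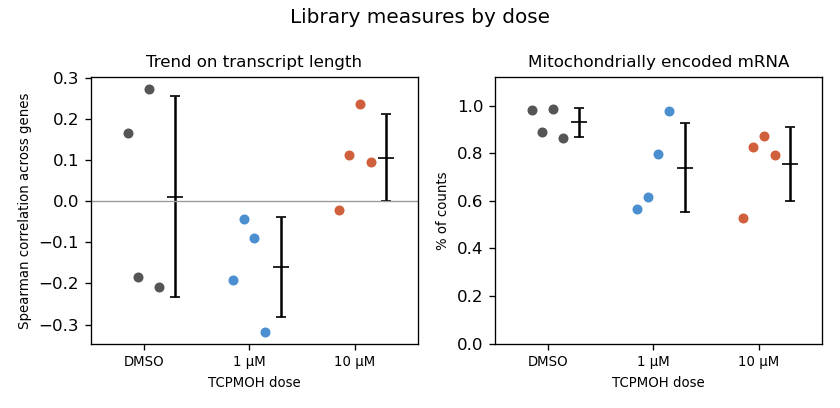
Left, Spearman correlation across genes between a library's deviation from the mean and transcript length, and right, the percentage of counts from mitochondrially encoded mRNA, for each library (points) by dose with group mean and SD (n = 4). On the left the 10 µM libraries averaged 0.106, the 1 µM libraries -0.160 and the DMSO libraries 0.0115, with DMSO from -0.208 to 0.273.

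Camera called 15 lists between the doses, 6 up and 9 down, and 3 kept the call with an estimated correlation. NRF2 targets were lower, with 5 of 20 members called, among them TXNRD1 (-0.27), NQO1 (-0.31) and the ferritin light chain FTL (-0.26), and 10 lower when adjusted over the list alone. NF-κB and cytokine genes were higher, with BIRC3 and TNFAIP3 (0.59) called of 18 and 7 higher when adjusted over the list alone. Genes of trophoblast invasion were higher, with PLAU (0.47) and MMP1 (0.84) called of 22 and 5 higher when adjusted over the list alone. These 3 lists each had an adjusted p = 0.0325 with an estimated correlation. FTL, TNFAIP3, PLAU and MMP1 lost the call without 1 µM replicate 4, with adjusted p of 0.147, 0.0997, 0.0635 and 0.184, and all but PLAU also without 1 µM replicate 3 or 10 µM replicates 2 or 3, FTL and MMP1 without 1 µM replicate 1, and MMP1 without 1 µM replicate 2 or 10 µM replicate 1. The other 12 called lists covered p53 targets, immediate early genes, placental hormones and trophoblast identity (up) and G1/S, G2/M, steroidogenesis, cholesterol synthesis, oxidative phosphorylation, heat shock, interferon response and ribosomal proteins (down). They had adjusted p with an estimated correlation from 0.193 to 0.590. The G2/M list was down although its only called member, MKI67 (0.40), was higher, with 2 higher and 0 lower when adjusted over the list alone. MKI67 lost its call without 1 µM replicates 1, 3 or 4 or 10 µM replicates 2 or 3 (adjusted p 0.0765 to 0.147). Of the 12 lists, p53 targets were up with GDF15 called of 21 and adjusted p = 0.283 with an estimated correlation, and immediate early genes were up with KLF6 (0.24) called of 22 and the same adjusted p. KLF6 lost its call without 1 µM replicates 3 or 4 or 10 µM replicate 3 (adjusted p 0.0583 to 0.0984), and camera called 9 lists without 1 µM replicate 2. CDKN1A was at 0.23 (adjusted p = 0.0920).

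The doses were then compared for shared changes. The doses shared 0 called genes, and unchanged groups against the same controls shared 0.040 on average in 50 simulated draws. For independent lists the expected overlap was 0 in each direction, since the lower dose had 0 calls. With the replicate block the doses shared 19 called genes. The correlation of log2 fold changes across genes was 0.489, where genes are not independent replicates. Unchanged groups simulated against the same controls gave 0.473 to 0.518, so the observed correlation lay within the range that shared controls alone gave. The covariance was 0.0209 against a mean of 0.0158 in the simulation, a difference of 0.00511, and it lay above the range of the draws, 0.0146 to 0.0168. The simulated genes were drawn independently of each other, without the length and GC trends of the libraries. That range therefore cannot decide on a covariance beyond that of shared controls. With the DMSO libraries split so that each dose had its own pair, the correlation averaged 0.060 over 6 assignments, from -0.02 to 0.148. The covariance averaged 0.00351, from -0.00125 to 0.00839.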

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

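Of the tests reported here, those of the length trend, and of the GC and length trend together, for genes that stayed called, of 1 µM replicate 4, of the NRF2 targets and of the mitochondrial share were chosen after the result was seen.

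In 15 of 237 groups of 4 libraries, 1 library lay far from the other 3, where 11.85 would be expected, since chance flags about 1 in 20 groups. In DMSO, TXNRD1 was at 1229 CPM in replicate 4 against 1133 to 1144 in the others, and P4HA1 at 86.8 CPM in replicate 2 against 92.2 to 93.1. At 1 µM, the total count of replicate 2 was 33.2 M against 18.9 to 19.5 M. CXCL8 was at 9.61 CPM in replicate 1 against 5.79 to 6.30, SPRY2 at 21.5 CPM in replicate 1 against 18.6 to 18.9, and ADM at 42.1 CPM in replicate 3 against 40.1 to 40.3. At 10 µM, the total count of replicate 4 was 32.9 M against 17.6 to 19.5 M, and the first principal component of replicate 1 was -33.4 against 3.03 to 6.43. The replicate 1 libraries of DMSO and 1 µM were also negative on that component, at -11.1 and -13.3. In 10 µM replicate 4, DOCK4 was at 8.88 CPM against 12.2 to 12.4, MT1X at 14.9 CPM against 15.9 to 16.0, NDRG1 at 73.9 CPM against 55.7 to 57.4 and AHNAK2 at 38.5 CPM against 37.2 to 37.4. ID2 was at 9.25 CPM in 10 µM replicate 3 against 10.5 to 10.7, and ADM at 40.8 CPM in the same library against 37.2 to 37.8. POSTN was at 23.7 CPM in 10 µM replicate 1 against 28.97 to 29.4.

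At 10 µM against DMSO, 1 of 35 splits of the 8 libraries gave as many called genes (207 against at most 69 in the other splits). At 10 µM against 1 µM it was also 1 of 35 (178 against at most 0). These shares argue against chance but cannot exclude it, since they are the smallest that 35 splits can give and were not adjusted. For the lists at 10 µM against 1 µM the share passed (1 of 35, the smallest it can be) by a margin of 1 list, 15 against at most 14. That count ran from 9 to 17 without 1 library and was 3 with an estimated correlation, so chance was not firmly excluded. It could not be excluded for the lists at 10 µM against DMSO (3 of 35, 14 against at most 14) or for the lists at 1 µM against DMSO (13 of 35, 7 against at most 12). For the genes at 1 µM against DMSO edgeR called 0 (1446 at an unadjusted p under 0.05, DESeq2 40, limma-voom 0), so all 35 of 35 splits gave as many by construction and the splits, with at most 1 gene in the others, say nothing about chance.

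At 10 µM against 1 µM, 157 genes were higher and 21 lower, and the higher genes had long transcripts. With offsets that took the correlation of fold change with length from 0.255 to -0.0251, 96 genes stayed called, 80 higher and 16 lower. Their median size was 0.43 before and 0.35 after, and the correlation with GC content was left at 0.114. This argues against a length trend over all genes as the whole cause. The genes called higher with these offsets still had a median length of 6001 bases, against 3535 for all genes. A length effect on these calls was therefore not excluded. With repeated offsets, which took the GC correlation to 0.00604, 73 stayed called, a share of 0.410 between the bounds, so the trend on GC content and length together and a response to dose cannot be told apart. The 82 genes that lost the call with the first offsets stay open too, since they were chosen for losing it and the ratio of their sizes, 0.650 (0.32, SE 0.07, before and 0.21, SE 0.06, after), decides nothing beyond the calls having ended as sizes fell. Without 1 µM replicate 4 the ratio of sizes was 0.940, with 178 of 178 genes in the same direction, although 20 genes were called. The 178 genes were chosen on these libraries and 173 were fully separated, so the ratio could hardly fall far. It cannot decide on a cause in that library alone.

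NRF2 targets, among them HMOX1, TXNRD1 and NQO1, were lower at 10 µM. The offsets for GC content and length left correlations of 0.0185 and -0.00228 with them here. With these offsets the median change of the 7 called members was 1.03 times as large, which argues against that trend as the cause for these 7. Without the 3 libraries numbered 1 it was 1.15 times as large. The 7 members were chosen on these libraries, so the latter ratio could hardly fall far. It cannot decide on those 3 libraries as a cause. Without HMOX1 the list had a camera p of 0.00162 with an estimated correlation, so HMOX1 alone did not account for the fall. The list was also lower at 10 µM than at 1 µM (p = 0.0028 with an estimated correlation), but that comparison uses the same 10 µM libraries and is no independent test of a response that differs between the doses. A lower NRF2 activity at 10 µM may be the reason, but NRF2 protein was not measured, and a difference in culture conditions between wells stays open.

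Mitochondrially encoded mRNAs were lower in the TCPMOH libraries by camera at the preset correlation. Variation between libraries in the mitochondrial share could account for this, since the groups overlapped and the exact permutation p was 0.0571 at 10 µM and 0.114 at 1 µM (n = 4 each). The members moved together, with an estimated correlation of 0.891, so they count as few independent values. An effect of TCPMOH on these mRNAs stays open.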

How the results depend on the processing

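The offsets for GC content and length, alone, repeated, with the block or with an estimated correlation, the block with an estimated correlation, and the fits without the 3 libraries numbered 1 were chosen after seeing the data. The setting foreseen for identical files did not apply, since no pair of libraries agreed within sampling noise.

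Over the alternatives, 1849 of the values of named genes kept direction and side of the threshold, 153 dropped below it, 51 passed it and 7 changed sign. The list results stayed on their side in 487 cases and lost the call in 233. At 10 µM against DMSO, 207 genes became 422 with no filter on low counts (416 of them pass the filter), 135 with the compared groups fitted alone, 12 at a log2 change of at least 1, and 106 at an adjusted p under 0.01. Leaving out 1 library gave 102 to 273, with 134 without DMSO replicate 2 and 102 without DMSO replicate 4. At 1 µM against DMSO, 0 genes in edgeR (1446 at an unadjusted p under 0.05, limma-voom 0) became 194 with no filter (all 194 pass it), 40 with DESeq2, 3 without the libraries numbered 1, 2 with the repeated offsets, and 0 to 1 without 1 library of the compared groups, the 1 being without 1 µM replicate 1. It became 2 without 10 µM replicate 1, which enters the shared fit. At 10 µM against 1 µM, 178 genes became 525 with no filter (521 of them pass it), 342 with DESeq2, 350 with the compared groups fitted alone, 87 with the repeated offsets, 0 at a log2 change of at least 1 (edgeR, 1930 at an unadjusted p under 0.05), 22 at an adjusted p under 0.01 and 20 to 247 without 1 library. That count was 100, 49 and 20 without 1 µM replicates 1, 3 and 4, and 83 and 31 without 10 µM replicates 2 and 3. A stricter threshold lowers a count by construction, and for the others the cause was not tested.

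Lists called at 10 µM against DMSO went from 14 to 4 with an estimated correlation, with or without offsets of either kind, to 5 with fry and to 8 to 12 without 1 library. At 1 µM they went from 7 to 0 with an estimated correlation, with or without offsets of either kind, to 0 with fry and to 5 to 7 without 1 library. Between the doses they went from 15 to 3 with an estimated correlation, with or without offsets of either kind, to 6 with fry and to 9 to 17 without 1 library. The overlap of calls at both doses went from 0 to 3 without the libraries numbered 1, to 2 with the repeated offsets, to a mean of 0.833 with split controls and to 0 to 1 without 1 library. The correlation of fold changes went from 0.489 to 0.060 with split controls and to 0.421 to 0.566 without 1 library.

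The labels give 4 independent experiments but do not say whether libraries with 1 number were made together, so the replicate block was used only as an alternative. Deviations from the group means had a correlation from 0.000466 to 0.228 (mean 0.0786) between libraries sharing a number. For different numbers the mean was -0.03. The correlation was over 0.1 in 4 of 12 pairs sharing a number and in 1 of 36 other pairs. Of 12 libraries, 7 were closest to their own number. On the first principal component the 3 libraries numbered 1 were negative, at -11.1, -13.3 and -33.4, and all libraries numbered 2 to 4 were positive. With the replicate block, 412 genes were called at 10 µM against DMSO, 51 at 1 µM against DMSO, with MMP1 (0.67, adjusted p = 0.000976) and CXCL8 (0.81, 0.00959) among them, and 511 between the doses, with 19 shared by both doses. With the block and the offsets the counts were 584, 28 and 480. With the block and an estimated correlation, 4, 0 and 1 lists were called. The cause was not tested.

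The signs that changed belonged to log2 values that passed no test in that comparison. Without 1 library, CYP1B1 at 10 µM ranged from -0.31 to 0.0475, above 0 without 10 µM replicate 1 and DMSO replicate 3. DDIT3 at 10 µM ranged from -0.0398 to 0.0961, below 0 without 10 µM replicate 1 and DMSO replicate 3, and was at -0.0240 without the libraries numbered 1. NQO1 at 1 µM ranged from -0.0407 to 0.00691, above 0 without 1 µM replicate 2 and DMSO replicate 4.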

Other observations

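The 3 lists below were chosen after the genes called at 10 µM were seen, and the tests on members whose values had not been looked at were written before those values were read. It was known that none of these members was called, so the tests were not blind to that.

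Several called genes are targets of BMP and SMAD signalling, which drives the inhibitors of DNA binding. ID1 (-0.24), ID2 (-0.65), ID3 (-0.41), ID4 (-0.60), SMAD6 (-0.57), ATOH8 (-0.85) and DLX2 (-0.64) were lower at 10 µM against DMSO, and lower BMP signalling is a candidate explanation. The other 12 tested members of the list did not move as a set, with 5 above 0, 7 below 0, a median of -0.04 and an adjusted p of 0.537 with an estimated correlation, so the question was left open.

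Genes induced by ERK signalling, such as DUSP6 and SPRY2, were higher at 10 µM in 6 of 10 members already seen. Higher ERK output might account for them. Of 11 other members 10 were above 0 at 10 µM, with a median of 0.09, but the adjusted p was 0.154 with an estimated correlation (0.0514 before adjustment over the 3 lists), which did not pass.

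Among 7 targets of YAP and TEAD already seen, AMOTL2 (-0.22), CCN2 (-0.35), ANKRD1 (-0.53) and TGFB2 (-0.55) were lower at 10 µM, and NT5E (0.52) was higher. Lower YAP activity could account for the falls but not for the rise, and 15 other members had 8 above 0 and 7 below 0, a median of 0.01 and an adjusted p of 0.714 with an estimated correlation.

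Of the 207 genes called at 10 µM, 186 had the same sign at 1 µM (89.9%, against 64.8% of all genes), with a median ratio of 0.277. Both comparisons used the same DMSO libraries. With the DMSO libraries split between the doses, 34.8% to 97.8% of the genes called had the same sign, depending on the assignment, against 45.4% to 55.3% of all genes. The share was higher in the called genes than in all genes in 5 of 6 assignments, and lower in the assignment with 371 called genes.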
